A study of Caenorhabditis elegans with 36 samples.

How the data were processed

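Total RNA of whole larvae was extracted with Trizol, labelled with biotin and hybridized to the single-colour Affymetrix C. elegans Genome Array, per the labels' protocols. The same protocol text stands with every sample: larvae were fed for 4 h, exposed to UV and harvested 6 h later. How the starved larvae were handled, the alleles of the mutants and the UV dose used for each array are not given in the sources used here. The authors summarized the arrays with Affymetrix Power Tools, per the submitters' processing notes, which give neither a version nor an algorithm. The deposited table holds log2 values, between 2.63 and 14.9, for 22625 probe sets on 36 arrays; the unit was read from that range, since no header names it. Medians and quartiles of the arrays were nearly equal, so the values were taken as already normalized between arrays by the authors and were used as deposited.

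The 77 control probe sets were left out, which left 22548 probe sets. Gene names came from the platform's probe annotation, updated by gene identifier to current symbols. Of the probe sets tested, 20766 carried 1 symbol, 887 several and 895 none, and 65 symbols were kept as annotated because their identifier had no match. For values per gene, the probe set with the highest mean over all arrays represented each of 17118 genes, 2981 of which had more than 1. Of the probe sets tested, 6954 are marked as hitting several transcripts or carry several symbols.

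All contrasts came from one limma 3.58.1 model in R 4.3.3, with one mean per group, moderated variances with an intensity trend and 24 residual degrees of freedom. The adjusted p is that of Benjamini and Hochberg over the probe sets of a contrast, and standard errors use the moderated variance. Interactions are differences between the responses of 2 strains. Gene lists, 42 in number with 1609 measured members, were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and with an adjustment over 756 pairs of list and contrast. With the preset correlation 272 pairs were called. With a correlation estimated from the residuals 38 of these were called and 234 were not. Beside the adjusted p over all pairs, members of each list were also counted after an adjustment over the list alone.

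The groups, contrasts, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls among called probe sets with 1 symbol and groups that do not overlap, for UV in N2, starvation in N2 and the comparisons of untreated daf-2 with N2 and with daf-2;daf-16. It names the 5 largest of each direction for the other contrasts, members of the gene lists, and daf-2, daf-16 and egl-27. A gene is said to move by over 1.5 times where its fold change without one array or under another setting differs by that ratio. For a comparison of contrasts that share arrays, groups without any change were simulated against the same shared arrays.

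The code for probe set calls and list shifts was tested on simulated data with 200 changed probe sets before use. In UV against untreated in N2 it recovered 54 of 67 changes of 1.5-fold, 63 of 67 of 2-fold and 66 of 66 of 4-fold, with 7 false calls among 22548 probe sets. For the UV response of daf-16 against N2 these were 31 of 67, 58 of 67 and 66 of 66, with 12 false calls. A simulated shift of 0.5 in one list was called in 4 of 4 pairs that held it and in 0 of the other pairs of the 756, by camera. The simulated genes varied independently of each other, so this says nothing about false list calls from genes that vary together. Each simulated probe set also had the same spread in every group. In the data, daf-16 UV replicate 3 differed from replicates 1 and 2 with a standard deviation of 0.394 and 0.327. In untreated daf-16 these were 0.186 to 0.203. The simulated recovery and false calls therefore need not hold for contrasts with such arrays, as in the UV response of daf-16. Alternatives checked were quantile normalization, median centring, no intensity trend, array weights, a model of only the groups compared, the replicate number as a block, one probe set per gene, leaving out the dimmest 33.3% of probe sets or the shared probe sets, and leaving out each array in turn. Chosen after seeing the data were leaving out the 3 arrays that stood apart from their groups, and keeping daf-2;daf-16 untreated replicate 1 as the only array of its group.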

Results

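Gene expression was measured on 36 single-colour Affymetrix C. elegans Genome Arrays hybridized with total RNA from synchronized larvae of the first stage (L1). Larvae of the wild type N2 and of daf-16, daf-2 and daf-2;daf-16 mutants were left untreated, exposed to ultraviolet light (UV) or starved. This gave 12 groups of 3 arrays each, except starved daf-16 with 2 and starved daf-2;daf-16 with 4. daf-2 encodes the insulin/IGF receptor, and daf-16 encodes the FoxO transcription factor that the receptor restrains. The design asks which transcripts respond to UV and to starvation, and which of these responses depend on the receptor and on DAF-16. The number of arrays limits the precision of every value. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples. Changes are given as log2 fold changes ± standard error, and "called" means an adjusted p under 0.05 in limma over 22548 probe sets.

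The targeted genes were read in every group first. One daf-16 probe set of low signal had a mean log2 signal of 4.11 in untreated N2, 4.32 after UV and 4.57 in starvation. In daf-16 it read 3.72, 3.61 and 3.52, in daf-2 4.03, 4.52 and 4.59, and in daf-2;daf-16 3.70, 3.55 and 3.43, in the same order of treatments. Its untreated differences between strains were not called (-0.39 ± 0.12 for daf-16 against N2, adjusted p = 1.3e-01). Its starvation response was lower in daf-16 than in N2 (-0.655 ± 0.181, adjusted p = 3.8e-02) and higher in daf-2 than in daf-2;daf-16 (0.831 ± 0.165, adjusted p = 6.4e-04). The UV response differed likewise between daf-2 and daf-2;daf-16 (0.638 ± 0.171, adjusted p = 1.9e-02) but was not called between daf-16 and N2 (-0.319 ± 0.171, adjusted p = 3.1e-01). The daf-16 probe set used to represent the gene read 8.08 in untreated N2, 8.72 in daf-16, 8.10 in daf-2 and 8.50 in daf-2;daf-16, and was thus higher in daf-16 than in N2 (0.65 ± 0.10, adjusted p = 1.2e-04). A further daf-16 probe set was also higher there (0.886 ± 0.095, adjusted p = 2.4e-07), while another was not called (0.081 ± 0.118, adjusted p = 9.6e-01). Starvation raised the representing probe set in N2 by 1.23 ± 0.10, in daf-16 by 0.46 ± 0.11, in daf-2 by 0.72 ± 0.10 and in daf-2;daf-16 by 0.65 ± 0.09. In starved daf-2;daf-16 the probe set of low signal was called in the opposite direction (-0.271 ± 0.113, adjusted p = 4.2e-02). The daf-2 probe set used read 5.04 in untreated N2, 5.05 in daf-16, 5.11 in daf-2 and 4.99 in daf-2;daf-16. After UV it read 5.18, 4.92, 5.10 and 4.91, and in starvation 5.63, 5.48, 5.84 and 5.53. The alleles are not given in the sources used here, and a probe set that lies outside the deleted part of a gene checks nothing about the mutation.

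The arrays separated first by feeding: the first principal component carried 65.5% of the variance and set the starved groups apart, and the second carried 14%. Within groups, 3 arrays were taken as standing apart: replicate 4 of starved daf-2;daf-16, replicate 1 of untreated daf-2;daf-16 and replicate 3 of daf-16 after UV. On the first component, replicate 1 of daf-2;daf-16 after UV (18.2) also lay away from replicates 2 and 3 (38.2 and 35.6). The standard deviation of its differences from them was 0.219 and 0.235, and it was not counted among the 3. The mean log2 difference of the molting cycle genes from the average array set the untreated daf-2;daf-16 array and the daf-16 UV array apart from their groups. It read 1.27 and 1.12 in replicates 1 and 2 of daf-16 after UV but 0.42 in replicate 3, and 1.25 in replicate 1 of untreated daf-2;daf-16 but 0.63 and 0.62 in replicates 2 and 3. These genes, which oscillate with each larval stage, stood between 1.298 and 1.356 in untreated N2, between 0.702 and 0.719 in untreated daf-2 and between 0.195 and 0.461 in N2 after UV. Control differences between the 3' and 5' ends, signs of RNA quality, also moved with some treatments without overlap. Gapdh was lower in starved N2 (0.327 to 0.622) than in untreated N2 (0.726 to 0.911), and in daf-16 after UV (0.484 to 0.602) than untreated (0.619 to 0.859). Actin was higher in daf-2 after UV (0.873 to 1.116) than untreated (0.632 to 0.788), and lower in starved daf-16 (0.507 to 0.583) than untreated (0.671 to 0.739). Ubiquitin was higher in starved daf-16 (4.994 to 5.178) than untreated (4.81 to 4.97), and in starved N2 (4.931 to 5.06) than in N2 after UV (4.894 to 4.911).

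**Figure D1:**
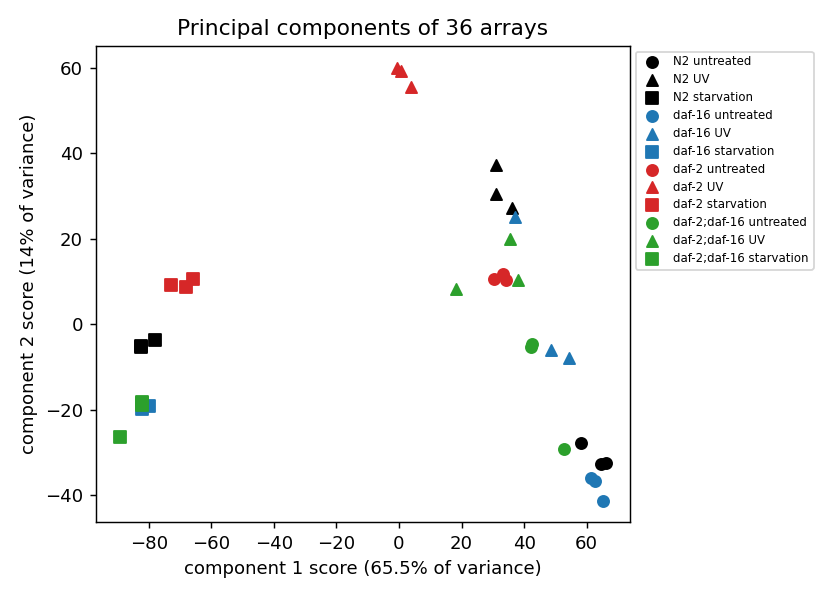
The arrays are placed by their scores on the first (x axis) and second (y axis) principal component of the log2 values; each point is one array, coloured by strain and shaped by treatment. The starved arrays lie apart from the fed ones along the first component, which carries 65.5% of the variance.

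**Figure D2:**
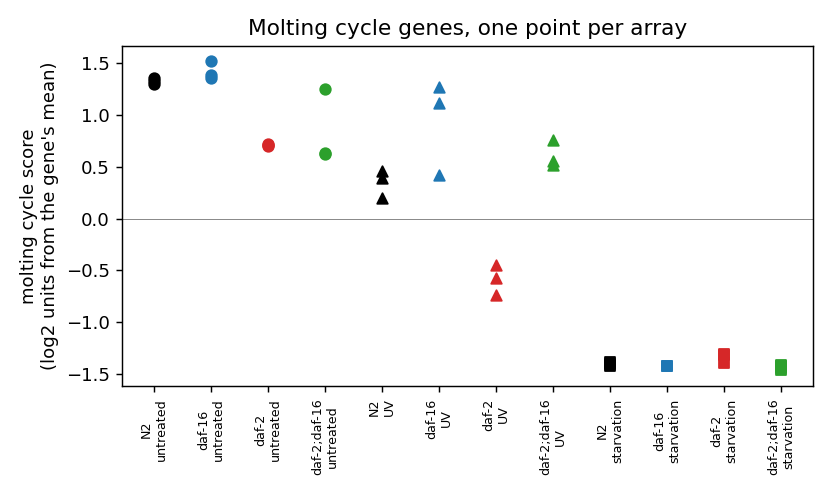
The y axis gives the mean log2 difference of the molting cycle genes from the average over all arrays, one point per array, for the 12 groups on the x axis. daf-16 UV replicate 3 (0.42) and daf-2;daf-16 untreated replicate 1 (1.25) lie away from the other arrays of their groups.

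Untreated daf-2 larvae carried high levels of textbook DAF-16 targets. mtl-1, a metallothionein, was higher than in N2 by 4.23 ± 0.20, the fatty acid and retinol binding protein gene far-3 by 4.38 ± 0.21, the small heat shock protein gene sip-1 by 3.42 ± 0.13 and the mitochondrial superoxide dismutase gene sod-3 by 3.36 ± 0.13 (n = 3 per group). The hedgehog-related genes grl-7 and wrt-4 were lower by 5.18 ± 0.57 and 4.29 ± 0.54. Of 23 measured DAF-16-activated genes, 18 were higher (18 adjusted over the list alone, median 0.85, adjusted p = 4.2e-21). Of 45 glutathione S-transferases, enzymes of detoxification, 27 were higher and 1 lower (29 and 2 adjusted over the list alone, adjusted p = 1.5e-15), with gst-14 at 2.26 ± 0.21 and gst-7 at 1.57 ± 0.12. Cytochrome P450 genes (28 of 73 higher, 4 lower; 30 and 5 adjusted over the list alone, adjusted p = 3.8e-06) and oxidative stress defence genes (12 of 31 higher, 3 lower; 14 and 3 adjusted over the list alone, adjusted p = 5.6e-07) shifted up as well. Genes of the glyoxylate cycle, gluconeogenesis and trehalose synthesis shifted up too, 10 of 21 being higher (12 adjusted over the list alone, adjusted p = 2.3e-06), among them the trehalose synthase gene tps-1 (1.22 ± 0.12) and pck-1, which encodes phosphoenolpyruvate carboxykinase (0.72 ± 0.16). Insulin-like peptide genes were higher for 8 of 24 (11 higher and 1 lower adjusted over the list alone, adjusted p = 2.1e-04, adjusted p = 2.7e-01 with an estimated correlation), led by ins-33 (3.10 ± 0.19) and ins-11 (2.78 ± 0.15). Molting cycle genes were lower for 19 of 43 and higher for 7 (21 and 7 adjusted over the list alone, adjusted p = 7.9e-04, adjusted p = 4.9e-01 with an estimated correlation). The proteasome was lower for 19 of 35 (28 adjusted over the list alone, adjusted p = 4.4e-10, adjusted p = 2.1e-01 with an estimated correlation). In all, 3783 probe sets differed, 2248 higher and 1535 lower, 824 of them by at least 2-fold. The Gapdh control difference between the 3' and 5' ends, a sign of RNA quality, was 0.293 to 0.548 in untreated daf-2 and 0.726 to 0.911 in untreated N2, while those of actin and ubiquitin overlapped. With array weights the count was 7084, and without shared probe sets 2310.

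The comparison of untreated daf-2 with daf-2;daf-16 asks which of these differences need DAF-16. far-3 (4.91 ± 0.21), mtl-1 (4.34 ± 0.20), sip-1 (3.59 ± 0.13) and sod-3 (3.06 ± 0.13) were higher in daf-2, as were the ferritin gene ftn-1 (2.50 ± 0.17) and gst-14 (3.07 ± 0.21). The lectin genes clec-10 (-3.30 ± 0.16) and clec-210 (-2.96 ± 0.23) and F19C7.2 (-3.14 ± 0.11) were lower. DAF-16-activated genes were higher for 15 of 23 (17 higher and 1 lower adjusted over the list alone, median 0.76, adjusted p = 3.8e-26). Glutathione S-transferases were higher for 22 of 45 and lower for 2 (24 and 3 adjusted over the list alone, adjusted p = 1.1e-12). Glycolysis genes were higher for 9 of 16 (12 adjusted over the list alone, median 0.36, adjusted p = 8.6e-12), among them gpi-1, the gene of glucose-6-phosphate isomerase (0.92 ± 0.08). Ribosome biogenesis genes were lower for 28 of 36 (32 adjusted over the list alone, median -0.53, adjusted p = 9.1e-22, adjusted p = 7.5e-02 with an estimated correlation), among them nol-58 (-0.85 ± 0.10) and the fibrillarin gene fib-1 (-0.81 ± 0.11). Their median was -0.21 with daf-2;daf-16 untreated replicate 1 as the only array of its group and -0.68 without it. Called probe sets numbered 2613 (1297 higher, 1316 lower; 402 by at least 2-fold), and the Gapdh difference in untreated daf-2;daf-16 was 0.607 to 0.713, again apart from daf-2. The count was 6126 with array weights, 1589 from these groups alone and 1536 without shared probe sets. With daf-2;daf-16 untreated replicate 1 as the only array of its group, an alternative chosen after seeing the data, it was 1609.

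Untreated daf-16 differed from N2 in few transcripts. The beta-galactosidase gene bgal-2 was lower by 3.06 ± 0.33, scl-24 by 2.52 ± 0.17, the insulin-like gene ins-26 by 1.54 ± 0.13 and ftn-1 by 1.48 ± 0.17, while nhj-1, which encodes a factor of DNA end joining, was higher by 1.89 ± 0.10. sod-3 (0.47 ± 0.13, adjusted p = 6.1e-02) and mtl-1 (-0.60 ± 0.20, adjusted p = 1.9e-01) did not pass; without N2 untreated replicate 3 sod-3 passed (0.61). Cuticle collagens were higher for 7 of 147 (10 adjusted over the list alone, median 0.09, adjusted p = 3.8e-05, adjusted p = 4.6e-01 with an estimated correlation). Called probe sets numbered 322 (186 higher, 136 lower). The count was 172 without daf-16 untreated replicate 1, 183 without N2 untreated replicate 2, 763 with array weights, 663 from these groups alone and 211 without shared probe sets.

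In N2, 6 h after UV exposure, dod-22, a gene that DAF-16 represses, rose by 4.49 ± 0.27, the infection response gene irg-5 by 3.78 ± 0.24, the P-glycoprotein transporter gene pgp-8 by 3.81 ± 0.17 and gst-24 by 3.21 ± 0.18 (n = 3 per group). The collagen genes col-39 and col-80 rose by 4.02 ± 0.22 and 3.78 ± 0.25. grl-7 fell by 3.71 ± 0.57 and bah-1 by 3.66 ± 0.54. The molting cycle scores of N2 after UV lay below those of untreated N2 without overlap. For the changes after UV in N2, an effect of UV itself and another position in the larval cycle therefore cannot be told apart. Glutathione S-transferases rose for 22 of 45 and fell for 5 (25 and 5 adjusted over the list alone, adjusted p = 8.8e-07, adjusted p = 5.4e-02 with an estimated correlation), and UDP-glucuronosyltransferases, also of detoxification, rose for 27 of 64 and fell for 5 (31 and 6 adjusted over the list alone, adjusted p = 4.0e-05, adjusted p = 2.0e-01 with an estimated correlation). DAF-16-repressed genes rose for 9 of 14 (10 adjusted over the list alone, median 1.01, adjusted p = 1.1e-06), among them dod-17 (1.62 ± 0.16) and C32H11.4 (2.43 ± 0.17). DAF-16-activated genes also rose, 10 of 23 (10 adjusted over the list alone, median 0.17, adjusted p = 1.4e-03, adjusted p = 1.3e-01 with an estimated correlation), with sip-1 at 1.96 ± 0.13, dod-3 at 1.76 ± 0.27 and sod-3 at 0.70 ± 0.13.

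Ribosome biogenesis genes rose for 22 of 36 and fell for 1 after UV in N2 (26 and 1 adjusted over the list alone, adjusted p = 8.8e-07, adjusted p = 4.1e-01 with an estimated correlation), among them the GTPase gene nog-1 (1.61 ± 0.12) and eif-6 (1.23 ± 0.14). Molting cycle genes fell for 30 of 43 and rose for 7 (31 and 7 adjusted over the list alone, median -1.04, adjusted p = 2.1e-08, adjusted p = 2.0e-01 with an estimated correlation), among them mlt-9 (-2.71 ± 0.31) and qua-1 (-2.94 ± 0.36). Neuron markers fell for 18 of 28 (18 adjusted over the list alone, adjusted p = 1.3e-07, adjusted p = 1.9e-01 with an estimated correlation), including the synaptic genes unc-13 (-0.96 ± 0.13) and snt-1 (-0.96 ± 0.14). Proteasome genes fell for 16 of 35 (16 adjusted over the list alone, median -0.18, adjusted p = 3.0e-05, adjusted p = 4.3e-01 with an estimated correlation). Of 25 nucleotide excision repair genes 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called (adjusted p = 8.4e-01). csb-1, which acts in transcription-coupled repair, rose by 0.63 ± 0.10, ddb-1 by 0.42 ± 0.09 and cyh-1 by 1.00 ± 0.12, while gtf-2H5 of the repair factor TFIIH fell by 0.81 ± 0.13. Checkpoint and apoptosis genes gave 1 rise and 2 falls among 21 (1 and 2 adjusted over the list alone, adjusted p = 7.7e-01): the checkpoint kinase gene atl-1 rose by 0.54 ± 0.09, whereas cep-1, the p53 homologue, was at 0.03 ± 0.10 (adjusted p = 8.5e-01) and its target egl-1 at 0.19 ± 0.11 (adjusted p = 2.2e-01). UV called 6496 probe sets in N2 (3063 higher, 3433 lower; 1213 by at least 2-fold), and 3966 without shared probe sets. Simulated changes of 1.5-fold in this comparison were recovered in 80.6% of cases, of 2-fold in 94%, and of 4-fold in 66 of 66.

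Among the largest rises after UV in N2, dod-22 rose in the mutants as well, by 3.60 ± 0.27 in daf-16, 4.67 ± 0.27 in daf-2 and 3.94 ± 0.27 in daf-2;daf-16, as did C49G7.12, by 3.50 ± 0.18, 3.97 ± 0.18 and 3.68 ± 0.18. DAF-16-repressed genes rose for 8, 9 and 8 of 14 (8, 9 and 8 adjusted over the list alone, median 0.61, 0.67 and 0.79); the adjusted p was 5.2e-06 in daf-16 (adjusted p = 5.2e-02 with an estimated correlation), 4.1e-06 in daf-2 (adjusted p = 5.1e-02 with an estimated correlation) and 5.1e-09 in daf-2;daf-16. Glutathione S-transferases rose for 21 of 45 and fell for 2 in daf-16 (22 and 2 adjusted over the list alone, adjusted p = 3.0e-09), and rose for 22 and fell for 4 in daf-2;daf-16 (24 and 5 adjusted over the list alone, adjusted p = 4.0e-10). Ribosome biogenesis genes rose for 24 of 36 in daf-16 (29 adjusted over the list alone, adjusted p = 3.6e-12, adjusted p = 2.2e-01 with an estimated correlation). In daf-2 they rose for 30 (31 adjusted over the list alone, median 0.73, adjusted p = 5.9e-19, adjusted p = 1.1e-01 with an estimated correlation), with nol-58 at 1.02 ± 0.10. Replication genes fell in daf-2 for 26 of 37 (28 fell and 1 rose adjusted over the list alone, adjusted p = 1.8e-10, adjusted p = 1.3e-01 with an estimated correlation) and in daf-2;daf-16 for 20, with 1 rise (27 and 1 adjusted over the list alone, adjusted p = 3.8e-09, adjusted p = 1.7e-01 with an estimated correlation). mcm-7, a subunit of the replicative helicase, fell by 0.89 ± 0.12 and 0.54 ± 0.12. Lysozyme, saposin-like and antimicrobial peptide genes rose for 24 of 71 in daf-2;daf-16 and fell for 1 (25 and 1 adjusted over the list alone, adjusted p = 1.1e-09). Of 147 cuticle collagens, 38 rose and 16 fell in daf-2 (42 and 16 adjusted over the list alone); their median was 0.22, their mean was -0.02, and the test called the list up (adjusted p = 1.6e-02, adjusted p = 7.0e-01 with an estimated correlation).

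Molting cycle genes fell after UV in daf-2 for 23 of 43 and rose for 3 (23 and 4 adjusted over the list alone, median -0.85, adjusted p = 4.4e-12, adjusted p = 1.1e-01 with an estimated correlation), with noah-2 at -3.95 ± 0.27. In daf-16 they fell for 23 and rose for 6 (27 and 6 adjusted over the list alone, median -0.54, adjusted p = 3.5e-04, adjusted p = 4.5e-01 with an estimated correlation). Without daf-16 UV replicate 3, the array with the low molting score, the daf-16 median was -0.34 and the list was not called. UV called 4288 probe sets in daf-16 (59.2% higher), 5629 in daf-2 and 3293 in daf-2;daf-16 (48.1% higher). At least 2-fold were 345 rises and 339 falls in daf-16, 517 and 451 in daf-2, and 333 and 14 in daf-2;daf-16, against 569 and 644 in N2. The daf-16 count was 2369 without daf-16 UV replicate 3 (70.2% higher), 1970 from these groups alone (76.0% higher) and 2666 without shared probe sets. The daf-2 count was 3392 without shared probe sets. The daf-2;daf-16 count was 5477 with array weights, 1715 from these groups alone (59.2% higher) and 1865 without shared probe sets.

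Interaction tests asked whether the UV response differed between strains. The responses of sip-1 (-0.98 ± 0.18), far-3 (-1.46 ± 0.29) and clec-174 (-1.56 ± 0.25) were lower in daf-16 than in N2, and that of F25D1.3 was higher (1.59 ± 0.32). DAF-16-activated genes were lower in the interaction for 4 of 23 (4 adjusted over the list alone, median -0.16, adjusted p = 3.5e-03, adjusted p = 1.7e-01 with an estimated correlation), and molting cycle genes higher for 1 of 43 (10 adjusted over the list alone, median 0.45, adjusted p = 2.8e-05, adjusted p = 3.8e-01 with an estimated correlation). The interaction called 417 probe sets (56.4% higher). Leaving out any one of its 12 arrays moved that count by over 1.5 times, from 97 without N2 UV replicate 2 to 1493 without daf-16 UV replicate 3. It was 2444 with array weights, 38 from these groups alone (18.4% higher), 187 without shared probe sets and 2173 without the 3 arrays standing apart, the last chosen after seeing the data.

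Between daf-2 and N2, the UV responses of nhr-23, a nuclear receptor gene of the molting cycle (-1.15 ± 0.17), and of lpr-4, a lipocalin-related gene (-2.63 ± 0.53), were lower in daf-2, and those of ribosome biogenesis genes were higher for 7 of 36 (14 adjusted over the list alone, median 0.34, adjusted p = 6.0e-11, adjusted p = 2.5e-01 with an estimated correlation), with wdr-12 at 0.87 ± 0.16. grd-5 (3.42 ± 0.62) and elf-1 (3.30 ± 0.69) were higher in the interaction, and ins-11 lower (-2.36 ± 0.21). Between daf-2 and daf-2;daf-16, ribosome biogenesis genes were higher in the interaction for 29 of 36 (31 adjusted over the list alone, median 0.74, adjusted p = 2.0e-31), including nol-16 (1.27 ± 0.17) and wdr-12 (1.16 ± 0.16). That median was 0.43 with daf-2;daf-16 untreated replicate 1 as the only array of its group and 0.91 without it. After UV in daf-2;daf-16 itself the list was not called (median -0.06), but stood at 0.27 with that replicate alone and at -0.23 without it. Molting cycle genes were lower for 18 of 43 (21 adjusted over the list alone, median -0.59, adjusted p = 1.4e-20). Their median was -0.49 with that replicate alone and -0.76 without it. The collagen gene dpy-7, a member of the cuticle collagens and not of the molting list, was also lower (-3.46 ± 0.44). These interactions called 1050 and 1228 probe sets. The first was 678 without N2 untreated replicate 3, 2618 with array weights and 671 without shared probe sets. The second was 1937 without daf-2;daf-16 untreated replicate 1 and 540 with it as the only array of its group, 2391 without the 3 arrays standing apart, 3679 with array weights and 778 without shared probe sets.

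Starvation of N2 called 11963 of 22548 probe sets, 6383 higher and 5580 lower. The acyl-CoA synthetase gene acs-2 rose by 6.03 ± 0.50, C18H7.1 by 7.12 ± 0.52, the flavin monooxygenase gene fmo-2 by 5.52 ± 0.37, the lipase gene lipl-3 by 4.00 ± 0.31 and the linker histone gene hil-1 by 4.08 ± 0.14 (n = 3 per group). dbd-2 fell by 8.92 ± 0.36, the cuticle-associated gene sym-1 by 8.19 ± 0.22 and the protease inhibitor-like molting gene mlt-11 by 7.84 ± 0.35. Molting cycle genes fell for 32 of 43 and rose for 7 (34 and 7 adjusted over the list alone, median -2.62, adjusted p = 1.2e-09, adjusted p = 1.7e-01 with an estimated correlation). Proteasome genes fell for 34 of 35 and rose for 1 (34 and 1 adjusted over the list alone, median -1.73, adjusted p = 1.7e-25), with pas-7 at -2.93 ± 0.12. Replication genes fell for 34 of 37 (34 adjusted over the list alone, adjusted p = 7.2e-14, adjusted p = 6.5e-02 with an estimated correlation), with mcm-7 at -2.59 ± 0.12, and mitosis genes fell for 33 of 41 and rose for 2 (33 and 2 adjusted over the list alone, median -1.07, adjusted p = 6.8e-11), with cdk-1 at -2.66 ± 0.09. Genes of the unfolded protein response of the endoplasmic reticulum fell for 18 of 28 and rose for 1 (18 and 2 adjusted over the list alone, median -0.68, adjusted p = 2.0e-07), with the chaperone gene hsp-3 at -2.69 ± 0.09 and the protein disulfide isomerase gene pdi-2 at -3.30 ± 0.09.

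Neuropeptide genes of the FMRFamide family rose under starvation in N2 for 24 of 25 (24 adjusted over the list alone, median 1.48, adjusted p = 3.9e-12, adjusted p = 2.0e-01 with an estimated correlation), with flp-3 at 2.32 ± 0.14. Neuron markers rose for 22 of 28 and fell for 1 (22 and 1 adjusted over the list alone, median 1.14, adjusted p = 5.9e-07, adjusted p = 2.1e-01 with an estimated correlation), among them the proprotein convertase gene egl-3 (1.76 ± 0.11). Pharynx markers, of another tissue, rose for 12 of 16 and fell for 4 (12 and 4 adjusted over the list alone, median 1.13, adjusted p = 3.7e-03, adjusted p = 7.6e-02 with an estimated correlation). Autophagy and lysosome genes rose for 24 of 33 and fell for 4 (25 and 4 adjusted over the list alone, median 0.65, adjusted p = 7.6e-06, adjusted p = 7.6e-02 with an estimated correlation), with lgg-2 at 2.34 ± 0.18 and atg-18 at 1.78 ± 0.10. DAF-16-activated genes rose for 18 of 23 and fell for 2 (18 and 2 adjusted over the list alone, median 0.86, adjusted p = 2.5e-05), including sod-3 (2.29 ± 0.13), mtl-1 (2.95 ± 0.20), sip-1 (2.24 ± 0.13) and the transhydrogenase gene nnt-1 (3.54 ± 0.18). Components of the insulin/FoxO pathway rose for 13 of 17 and fell for 3 (13 and 3 adjusted over the list alone, median 0.59, adjusted p = 1.6e-02, adjusted p = 4.1e-01 with an estimated correlation), among them the kinase gene pdk-1 (1.27 ± 0.10). egl-27, a regulator with a GATA-type domain, rose in each strain, by 0.98 ± 0.09 in N2, 0.98 ± 0.10 in daf-16, 0.84 ± 0.09 in daf-2 and 0.95 ± 0.08 in daf-2;daf-16.

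In the starved mutants the proteasome fell again, for 34 of 35 genes, also 34 adjusted over the list alone, in daf-16 (median -1.64), in daf-2 (-1.44) and in daf-2;daf-16 (-1.70, adjusted p at most 1.6e-24), and mcm-7 fell by 2.12 ± 0.14, 1.75 ± 0.12 and 2.55 ± 0.11. In starved daf-16 the DAF-16-activated genes gave 11 rises and 7 falls (11 and 8 adjusted over the list alone, median 0.07, adjusted p = 3.9e-01): sod-3 fell by 1.38 ± 0.15 and cdr-2 by 2.35 ± 0.13, and hil-1 rose by 2.34 ± 0.16. In starved daf-2;daf-16 sod-3 fell by 1.25 ± 0.12 and sip-1 by 0.62 ± 0.12. Called probe sets numbered 11547 in daf-16, 9692 in daf-2 and 12286 in daf-2;daf-16. Without shared probe sets these counts were 7454, 6058 and 7892, and that of N2 was 7583.

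The interaction of starvation with the daf-16 mutation asks which starvation responses need DAF-16. The responses of sod-3 (-3.67 ± 0.19), sip-1 (-2.62 ± 0.20), mtl-1 (-2.12 ± 0.30), nnt-1 (-2.15 ± 0.27) and hil-1 (-1.74 ± 0.22) were lower in daf-16 than in N2, and those of the arginine kinase gene argk-1 (2.18 ± 0.19) and clec-10 (1.90 ± 0.24) were higher. DAF-16-activated genes were lower for 7 of 23 (13 adjusted over the list alone, median -0.47, adjusted p = 9.2e-22), oxidative stress defence genes for 7 of 31, with 1 higher (9 and 3 adjusted over the list alone, adjusted p = 7.5e-06), and cuticle collagens for 16 of 147 (25 adjusted over the list alone, median -0.22, adjusted p = 1.8e-10, adjusted p = 2.1e-01 with an estimated correlation). The test called 676 probe sets, 291 higher and 385 lower. The count was 416 without daf-16 starvation replicate 1, 386 without replicate 2, 1672 with array weights, 1138 from these groups alone and 426 without shared probe sets. In this comparison 31.3% of simulated 1.5-fold changes and 79.1% of 2-fold changes were recovered.

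Between daf-2 and N2, the starvation response was lower in daf-2 for sip-1 (-2.80 ± 0.18), mtl-1 (-2.83 ± 0.28) and sod-3 (-2.52 ± 0.18), genes already high in untreated daf-2. DAF-16-activated genes were lower for 15 of 23 and higher for 1 (15 and 2 adjusted over the list alone, median -0.69, adjusted p = 6.8e-11), and glyoxylate, gluconeogenesis and trehalose genes for 7 of 21 (8 adjusted over the list alone, adjusted p = 2.4e-06). Between daf-2 and daf-2;daf-16, the superoxide dismutase gene sod-5 (2.69 ± 0.32), the cathepsin B-like gene cpr-2 (3.83 ± 0.18) and cdr-2 (1.89 ± 0.16) had higher responses in daf-2, and cpr-4 a lower one (-2.50 ± 0.13). Cuticle collagens were higher in that interaction for 49 of 147 (72 adjusted over the list alone, median 0.44, adjusted p = 1.3e-16, adjusted p = 9.1e-02 with an estimated correlation), and autophagy genes lower for 11 of 33 (18 adjusted over the list alone, adjusted p = 3.6e-06, adjusted p = 6.8e-02 with an estimated correlation). These interactions called 3348 and 2885 probe sets. With array weights they called 6030 and 5362, and without shared probe sets 2019 and 1729. With daf-2;daf-16 untreated replicate 1 as the only array of its group the second called 1900.

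**Figure D3:**
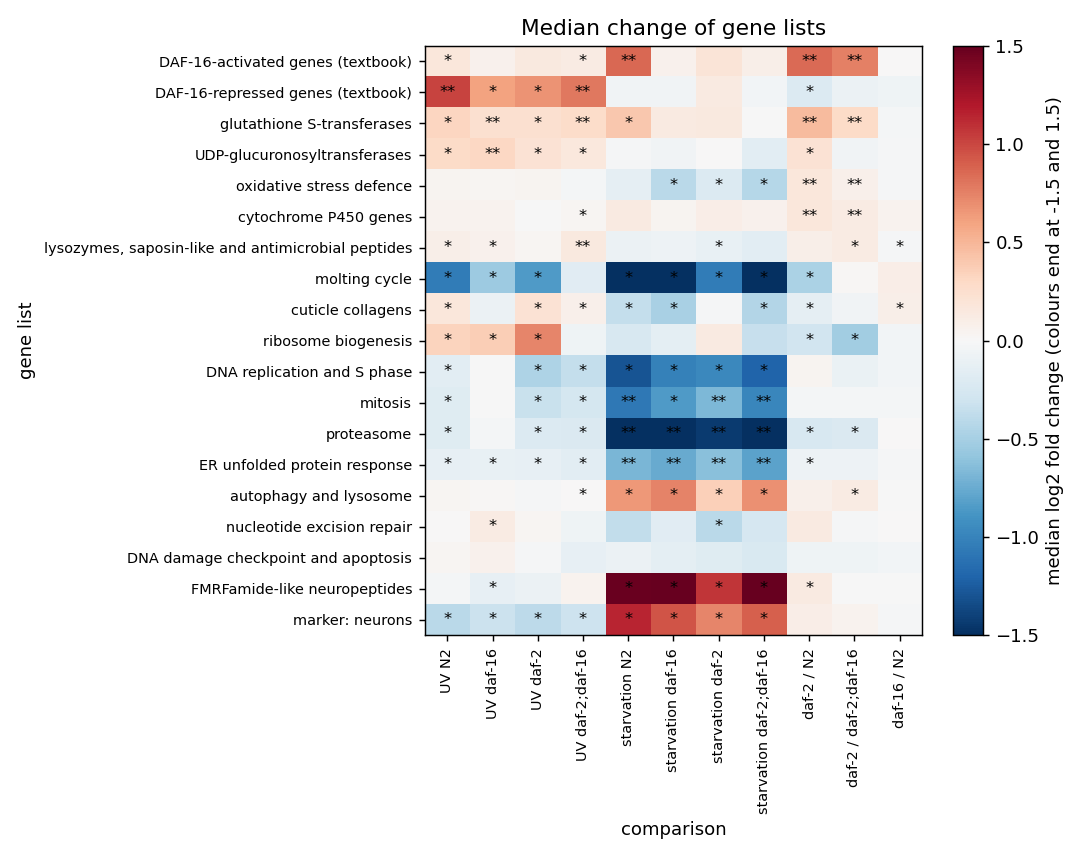
Each cell gives the median log2 fold change of a gene list (y axis) in a comparison (x axis), coloured from -1.5 to 1.5; one star marks a list called with the preset correlation and a pair of stars one also called with an estimated correlation. Proteasome genes fell in each starved strain, and DAF-16-activated genes were higher in untreated daf-2 than in N2 (0.85).

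Genes higher in untreated daf-2 than in daf-2;daf-16 by at least 2-fold, 209 with one probe set each, were followed through the treatments of the other strains; daf-2 and daf-2;daf-16 arrays take no part in those contrasts. After UV in N2, 121 rose and 20 fell (median 0.66, adjusted p = 3.1e-21). In the daf-16 mutant, 99 rose and 3 fell after UV (median 0.40, adjusted p = 7.0e-22). Under starvation 140 rose and 30 fell in N2 (median 1.16, adjusted p = 1.8e-12), and 108 rose and 52 fell in daf-16 (median 0.40, adjusted p = 5.8e-04, adjusted p = 2.3e-01 with an estimated correlation). In the interaction with daf-16 the starvation response was lower for 62 and higher for 6 (median -0.37, adjusted p = 2.5e-28). The UV response was lower for 15 and higher for 3 (median -0.24, adjusted p = 2.0e-05, adjusted p = 1.8e-01 with an estimated correlation). When the set took all called genes with no minimum fold, that median was -0.02, the UV medians were 0.18 in N2 and 0.18 in daf-16, the starvation median in N2 was 0.59 and that of its interaction -0.15. The study's own samples defined this set, so it is not an outside list.

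The 123 genes lower in untreated daf-2 than in daf-2;daf-16 fell after UV in N2 for 73 and rose for 19 (median -1.61, adjusted p = 8.2e-02 with an estimated correlation), and in daf-16 for 65 and 20 (median -0.95, adjusted p = 2.2e-01 with an estimated correlation). This set rested on single arrays. Without daf-2;daf-16 untreated replicate 1 the medians were 0.12 and 0.20. Without daf-2 untreated replicates 1, 2 and 3 in turn they were -0.23, -0.43 and -0.71 in N2 and -0.10, -0.25 and -0.29 in daf-16.

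UV and starvation in N2 called 3565 probe sets in the same direction, where 1717 were expected from the sizes of the responses, and 1507 in opposite directions, where 1730 were expected. Of the latter, 1012 fell after UV and rose in starvation. Across probe sets, which are not independent replicates, the changes correlated with r = 0.538. Both comparisons share the untreated N2 arrays. Simulated data with no change gave r = 0.501 from these shared controls alone, so r does not show how much of the likeness is real. The covariance was 0.00842 in the simulation against 0.275 in the data, which argues against the shared controls as its main source. Calls were not counted in the simulation, so the part of shared controls in the excess of calls was not tested. In the direct comparison, UV against starvation in N2, the proteasome was higher after UV for 33 of 35 and lower for 1 (33 and 1 adjusted over the list alone, median 1.58, adjusted p = 3.3e-22), and mitosis genes were higher for 33 of 41 and lower for 2 (33 and 2 adjusted over the list alone, median 1.01, adjusted p = 1.1e-09). Neuron markers were lower for 26 of 28 (26 adjusted over the list alone, median -1.58, adjusted p = 9.8e-13, adjusted p = 6.5e-02 with an estimated correlation). irg-5 (6.30 ± 0.24) and irg-4 (6.29 ± 0.20) were higher after UV, and acs-2 (-5.78 ± 0.50) and sod-3 (-1.58 ± 0.13) were lower. Called probe sets numbered 12943, and 8360 without shared probe sets.

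The responses of the strains were set side by side across probe sets. After UV, N2 and daf-16 shared 3117 calls of the same direction and 14 opposite (r = 0.821), N2 and daf-2 3879 and 55 (r = 0.760), and N2 and daf-2;daf-16 2457 and 17 (r = 0.687). Under starvation these were 9706 and 42 for daf-16 (r = 0.955), 8245 and 155 for daf-2 (r = 0.876) and 9857 and 120 for daf-2;daf-16 (r = 0.926). The slopes of the mutant response on that of N2 after UV were 0.587, 0.725 and 0.419, and under starvation 0.960, 0.658 and 0.831. The daf-16 slope after UV averages unlike arrays, whose shares of the N2 falls were 0.27, 0.37 and 0.99. The daf-2;daf-16 slopes use untreated replicate 1, which stood apart from its group. Noise in the N2 changes lowers such slopes by an amount not estimated here. These pairs of contrasts share no arrays.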

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

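All tests of explanations in this part were chosen only after the results were seen. The bound of the RNA degradation test was changed after its value was seen, and the splits with the mean strain difference removed were added after the plain splits.

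daf-2;daf-16 untreated replicate 1 stood apart from replicates 2 and 3, with a molting cycle score higher by 0.621, where the largest range within the other untreated groups was 0.164. A mislabelled sample with an intact daf-16 gene was argued against by its score of 0.774 over 412 probe sets, on a scale from 0 in untreated N2 to 1 in untreated daf-16. A mislabelled daf-16 single mutant was argued against by a score of 1.016 over 47 probe sets, on a scale from 0 in daf-16 to 1 in replicates 2 and 3. RNA degradation could not be decided, since 1 of 3 control differences between the 3' and 5' ends lay outside the range of the other untreated arrays; under the bound first written, that 1, ubiquitin at 5.13, would have counted for it. Another position in the molting cycle may account for the pattern and stays open, as does a separate batch of replicates 2 and 3, which the labels do not give and no test addressed.

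After UV, daf-16 replicates 1 and 2 showed less of the N2 response than replicate 3: their shares of the N2 rises were 0.68 and 0.61 against 0.91, and of the N2 falls 0.27 and 0.37 against 0.99. Replicate 3 as a mislabelled N2 sample was argued against by its score of 0.942 over 113 probe sets, on a scale from 0 in N2 after UV to 1 in replicates 1 and 2. A weaker exposure that shrinks rises and falls alike was argued against, since the share of falls over the share of rises was at most 0.607 in replicates 1 and 2. The molting cycle score of replicate 3 differed from the mean of the other replicates by -0.774, beyond the largest range of 0.285 within the other UV groups, so another position in the molting cycle may account for the pattern. The daf-2;daf-16 arrays after UV also had small shares of the falls (0.28, 0.15 and 0.30, with 0.58, 0.56 and 0.71 of the rises) and daf-2 arrays larger ones (0.62, 0.67 and 0.62, with 0.74, 0.82 and 0.80), so an effect of the daf-16 mutation stays open as well, not tested apart from molting position.

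Genes higher in untreated daf-2 than in daf-2;daf-16 rose after UV in N2 and also in daf-16. A rise that needs DAF-16 was argued against by their median of 0.398 after UV in daf-16, but only for the set of at least 2-fold: with no minimum fold the median was 0.176, still called but under the bound written for this test. That rise in daf-16 is part of the pattern itself, so the test restates it and adds no separate evidence. The molting position of the daf-2;daf-16 arrays that define the set was argued against as the whole cause: defined from replicates 2 and 3, nearer to untreated daf-2 in molting score, the set had a median of 0.293 in daf-16. Whether it carries part of the size stays open, and the molting position of the UV arrays themselves was not tested. That part of the rise comes from factors other than DAF-16 is a hypothesis, found and tested on the same data.

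The UV response differed between daf-16 and N2 for 417 probe sets, between daf-2 and N2 for 1050 and between daf-2 and daf-2;daf-16 for 1228, by the interaction test. The starvation response differed for 676, 3348 and 2885 in the same order, the first of these without splits because starved daf-16 has 2 arrays. Exchanging strain labels within treatments, 100 splits each, gave as many calls as the real split in 9 splits for the first (highest other 2504), 12 for the second (6502) and 8 for the third (3957), the real one included. For starvation it gave as many in 2 splits for daf-2 against N2 (highest other 3574) and in 4 for daf-2 against daf-2;daf-16 (4661). Such an exchange can carry the mean difference between strains into the interaction, so these splits cannot judge chance either way. Splits that call several times the real count point to a structure of the samples. With the mean strain difference removed, as many calls came in 4 of 100 splits for the UV response of daf-16 against N2 (highest other 2301) and in 1, the real one, for the other 4 (highest other 97, 1145, 663 and 853). For these 4 that argues against chance, and the difference between strains may carry their high plain splits. For daf-16 against N2 the share also lay under 0.05, but its high splits stay unexplained, so chance stays open there.

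The splits of single comparisons were as follows. For starvation in daf-2;daf-16, 1 of 35 splits, the real one, gave as many as its 12286 calls, and the highest other gave 9742. With 3 arrays against 3 the 10 splits are too few to judge chance; the real one was the 1 with as many calls in each. The real and highest other counts were 6496 and 0 for UV in N2, 4288 and 41 in daf-16, 5629 and 0 in daf-2, and 3293 and 116 in daf-2;daf-16. They were 11963 and 1 for starvation in N2, 9692 and 2 in daf-2, and 12943 and 834 for UV against starvation in N2. For untreated larvae they were 3783 and 0 for daf-2 against N2, 322 and 9 for daf-16 against N2, and 2613 and 63 for daf-2 against daf-2;daf-16.

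Starved daf-2;daf-16, the only group of 4, had an array far from the others in 11 of 52 measures. For a single measure chance sets 1 in 20 groups apart. The 52 measures come from the same 4 arrays and are not independent, so their number cannot be judged against that rate. The gap over the group's range, judged by Dixon's test, was 0.972, 0.927 and 0.894 for replicate 4 on the first 3 principal components. For its list scores it was 0.891 for cuticle collagens, 0.861 for DAF-16-repressed genes, 0.866 for FMRFamide-like neuropeptides, 0.93 for body muscle markers, 0.848 for recombination and translesion genes and 0.952 for the TCA cycle and respiratory chain. It was 0.869 for the actin difference between the 3' and 5' ends of replicate 4, and 0.922 for that of ubiquitin in replicate 2.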

How the results depend on the processing

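Leaving out the 3 arrays standing apart and keeping daf-2;daf-16 untreated replicate 1 alone were chosen after seeing the data, as was leaving out arrays for gene lists and for the sets from daf-2 against daf-2;daf-16. Of 318 counts of called probe sets under alternatives, 260 stayed within 1.5 times and 58 moved. Quantile normalization, median centring, no intensity trend, one probe set per gene, leaving out the dimmest 33.3% and the replicate block moved none of the 18 counts each. The deposited arrays already had nearly equal medians and quartiles. Quantile normalization and median centring were thus weak tests of how the counts depend on the authors' normalization. Of 8326 values of named genes, 8147 kept direction and side of the threshold, 163 fell below it, 15 passed it and 1 reversed. Of 3923 list values 3190 kept both, 531 became weaker, 198 stronger, and in 4 the test's direction turned, which can differ from the sign of the median. Each of 12 overlap values of UV and starvation stayed within 1.5 times, between 2988 and 3613. Where no reason is given, the cause was not tested. The pseudocount of 16 was not run, since the table holds log2 values. Signal over background limits dim genes: a low value cannot tell low expression from none, so changes there are less certain.

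Leaving out shared probe sets, 6954 of 22548, lowered each count. Each fell by a larger share than that of the probe sets left out. Testing fewer probe sets may thus account for only part of the drop, and the cause of the rest was not tested. UV gave 3966 in N2, 2666 in daf-16, 3392 in daf-2 and 1865 in daf-2;daf-16, and starvation 7583, 7454, 6058 and 7892. UV against starvation gave 8360. Untreated daf-2 against N2 gave 2310, daf-16 against N2 211 and daf-2 against daf-2;daf-16 1536. UV interactions gave 187 for daf-16 against N2, 671 for daf-2 against N2 and 778 for daf-2 against daf-2;daf-16, and starvation interactions 426, 2019 and 1729.

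With array weights, UV in daf-2;daf-16 gave 5477, untreated daf-2 against N2 7084, daf-16 against N2 763 and daf-2 against daf-2;daf-16 6126. UV interactions gave 2444, 2618 and 3679, and starvation interactions 1672, 6030 and 5362. With only the groups compared, UV gave 1970 in daf-16 and 1715 in daf-2;daf-16, untreated daf-16 against N2 663 and daf-2 against daf-2;daf-16 1589. The UV and starvation interactions of daf-16 against N2 gave 38 and 1138. This setting uses fewer samples, and most of these counts fell. Yet untreated daf-16 against N2 rose from 322 and the starvation interaction from 676. Fold changes are the same in both models, so these rises came from a smaller estimate of spread. Pairs of arrays differed with a standard deviation of 0.167 to 0.203 in untreated N2 and daf-16, and up to 0.394 in daf-16 after UV. Which arrays raised the estimate shared by all groups was not tested.

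Without the 3 arrays standing apart, the UV interaction of daf-16 against N2 gave 2173 and that of daf-2 against daf-2;daf-16 2391. With daf-2;daf-16 untreated replicate 1 alone, untreated daf-2 against daf-2;daf-16 gave 1609, its UV interaction 540 and its starvation interaction 1900; the lone array was assumed to vary like the other groups. Results not called with all arrays were called there on the other side: nol-58 after UV in daf-2;daf-16 (-0.07 to 0.38), glycolysis in the same comparison (0.02 to -0.14) and the molting cycle in untreated daf-2 against daf-2;daf-16 (0.02 to -0.25). Ribosome biogenesis after UV in daf-2;daf-16, not called at -0.06, was called at -0.23 without the 3 arrays and at -0.23 with only replicate 1 of untreated daf-2;daf-16 left out, and at 0.27 with that replicate alone.

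With an estimated correlation, 38 of 272 list calls and 4 of 11 set calls held. Medians do not change there; calls lost were those of the lower set after UV in N2 (-1.61) and daf-16 (-0.95), in starvation in N2 (-2.45) and daf-16 (-2.79) and in the UV interaction (0.45), and of the higher set in starvation in daf-16 (0.40) and the UV interaction (-0.24). With no minimum fold, the lower set reversed after UV in N2 (0.04) and daf-16 (0.11), shrank in starvation in N2 (-0.42) and daf-16 (-0.30), was called in the starvation interaction (0.14), and the higher set lost its call in the UV interaction (-0.015). The higher set kept its other calls there with smaller medians after UV in N2 (0.66 to 0.18) and daf-16 (0.40 to 0.18), in starvation in N2 (1.16 to 0.59) and in the starvation interaction (-0.37 to -0.15). Without the 3 arrays, the lower set reversed after UV in N2 (0.11) and daf-16 (0.15), shrank in starvation in N2 (-0.59) and daf-16 (-0.63), lost its call in the UV interaction (0.052) and gained one in that of starvation (0.10). With replicate 1 alone its starvation interaction was called lower (-0.24), where with all arrays a median of nearly the same size (-0.22) was not called.

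Leaving out 1 array in turn gave 2369 to 4659 for UV in daf-16, 172 to 250 for untreated daf-16 against N2, and 97 to 1493, 678 to 1158 and 865 to 1937 for the UV interactions. The starvation interaction of daf-16 against N2 gave 386 to 720; where this left 1 starved daf-16 array, the lone array was assumed to vary like the other groups. The lower set had medians of -1.99 to 0.12 after UV in N2, -1.46 to 0.20 in daf-16, -2.74 to -0.56 in starvation in N2, -3.35 to -0.58 in daf-16, 0.075 to 0.975 in the UV interaction and -0.30 to 0.11 in that of starvation, and reversed without daf-2;daf-16 untreated replicate 1 (0.12 and 0.20).

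Replicate numbers were tried as a block. Arrays of the same number correlated over 0.1 throughout in none of 12 comparisons, and only after UV in daf-16 did all 3 correlate best with their own number (0.09 to 0.36), so the numbers gave no evidence of pairing.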

Other observations

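All tests of explanations in this part were chosen after the results were seen, except that of the molting cycle list carrying the likeness between untreated daf-2 and UV.

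Genes of the intracellular pathogen response rose after UV in daf-16 for 8 of 27 (9 adjusted over the list alone, median 0.18, adjusted p = 5.1e-04, adjusted p = 1.2e-01 with an estimated correlation) and in daf-2;daf-16 for 8 (10 adjusted over the list alone, adjusted p = 5.6e-06). pals-6, a dim transcript of that list, rose by 1.45 ± 0.19 in daf-16 and 1.41 ± 0.19 in daf-2;daf-16 and stood at 0.11 ± 0.19 in N2 and 0.06 ± 0.19 in daf-2. Its interactions were 1.34 ± 0.26 for daf-16 against N2 and -1.35 ± 0.26 for daf-2 against daf-2;daf-16. pals-23 rose by 1.48 ± 0.12 and the cullin gene cul-6 by 1.29 ± 0.13 in N2.

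Starvation in N2 raised the cyclin-dependent kinase inhibitor genes cki-1 (0.94 ± 0.14) and cki-2 (1.04 ± 0.12) and the insulin-like gene ins-1 (1.97 ± 0.13), and lowered the insulin-like gene daf-28 (-0.70 ± 0.13). Genes of the glyoxylate cycle, gluconeogenesis and trehalose synthesis rose for 12 of 21 and fell for 2 (12 and 2 adjusted over the list alone, median 0.40, adjusted p = 2.7e-02, adjusted p = 3.7e-01 with an estimated correlation), with tps-1 at 2.39 ± 0.12. The fatty acid desaturase gene fat-5 rose by 3.35 ± 0.19. The chaperone genes hsp-4 of the endoplasmic reticulum (-2.59 ± 0.15) and hsp-60 of mitochondria (-2.34 ± 0.10) fell, and the small heat shock protein gene hsp-12.3 rose (2.64 ± 0.16). sod-5 rose by 2.55 ± 0.24 in starved daf-2 and stood at -0.14 ± 0.22 in starved daf-2;daf-16.

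Untreated daf-2 larvae differed from N2 in part the way UV-exposed larvae did. UV in daf-16 and daf-2 against N2, which share no arrays, called 1628 probe sets in the same direction (976 higher, 652 lower; 372 expected) and 191 in opposite directions (347 expected), and the changes correlated across probe sets, which are not independent replicates, with r = 0.584. Without molting cycle and cuticle collagen genes the correlation across 16928 genes was 0.563, so these lists did not carry the likeness by themselves. That part of the UV response is present in untreated daf-2 larvae is a hypothesis consistent with these counts. Other genes that follow larval age could also carry it, and this was not tested.

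Neuron markers and FMRFamide genes rose under starvation in N2 with the preset correlation but not with an estimated one (adjusted p = 2.1e-01 and 2.0e-01), and pharynx markers had nearly the same median (1.13) as neuron markers (1.14). A larger share of neuron RNA raising all neuron markers alike was argued against by the range between quartiles of the neuron and FMRFamide members, 0.822. No range of other genes was set beside it, so a larger share along with differences between genes stays open. A lower share of intestine RNA that raises markers of every other tissue alike was argued against by a spread of 1.69 between the medians of 4 marker lists, the lowest of them hypodermis (-0.55). The 4 lists were neurons, body muscle, pharynx and hypodermis. Intestine markers themselves took no part in this test, so the share of intestine RNA was not read directly. Hypodermis genes may have changed on their own, so a lower share of intestine RNA beside such a change stays open. Nothing here sets neurons apart from pharynx, so regulation of neuronal genes under starvation is no more than a hypothesis that separately measured neurons would test.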
